A study of Mus musculus with 10 samples.

How the data were processed

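The measurements come from 10 Agilent mouse oligonucleotide arrays with 2 colours. Per the labels, ovariectomized C57BL/6 mice received estradiol (E2) or the sesame oil vehicle, and uteri were taken at 30 min, 2 h, 6 h, 12 h and 24 h. RNA of 3 or 4 uteri was pooled per treatment group. Each time point has 2 arrays of the same pair of RNA pools with the dyes exchanged: E2 in Cy5 on replicate 1 and in Cy3 on replicate 2. The dye swap is technical, so each time point counts as 1 replicate. The labels give the control the same name at all times, and whether it was 1 pool or one per time is not given in the sources used here.

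The deposited scanner files hold spot intensity values, the mean brightness of each spot and the median of its surround in both channels, per the file headers not yet normalized. They also hold the scanner software's log10 ratio of Cy5 over Cy3. Per the file headers, Agilent Feature Extraction 7.5 made that ratio with spatial detrending and a rank-consistent LOWESS dye normalization, and limited it to 2 on either side of 0. The deposited p-value of each log10 ratio is the software's own error model for 1 array, and its flags mark spots that are outliers, saturated or well above background. The authors' deposited value table holds log10 ratios of E2 over control. Its direction and scale were settled against the scanner files. Between 486 and 945 of its 22393 spots per array differ from the turned software ratio by more than 1e-06. Its column medians lie between -0.0027 and 0.0027, so the columns are centred near 0.

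For the main values, normexp with an offset of 50 was applied to the mean signals with the median background, and each array was normalized by loess with control spots at weight 0 (limma 3.58.1, R 4.3.3). Ratios were turned to E2 over control on the log2 scale. Spots marked as outliers, 7 to 20 per array, were set to missing, spots of 1 probe were averaged, and a gene was represented by its probe with the highest mean intensity. Of 20868 probes, 8947 were named through their RefSeq accession in a gene table of assembly GRCm38.p6, 513 through the symbol in the file's description, and 11408 were kept under their accession. This left 20726 genes, 139 of them with more than 1 probe. No coordinates are given, since the array files name no genome build.

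At each time point a gene passed the size rule when its log2 ratio was at least 1, or at most -1, on both arrays and its probe was well above background in the channel of the brighter RNA on both. With 1 pool per treatment and time there is no test per time point and no p. The error given after ± is 0.5 of the difference between the 2 arrays, which measures hybridization and dye and leaves out the spread between animals and pools. The numbers of pools and arrays limit the precision. No gene named by the rule below needed a lower bound in place of a fold. Across time points, 19880 genes well above background in either channel on both arrays of at least 1 time point were fitted with limma on the 5 dye-swap means. The first fit set their mean against 0 and the second set the late times (12 and 24 h) against the early ones (30 min, 2 and 6 h), with Benjamini-Hochberg adjustment and a threshold of 0.05. Pools of different times served as replicates there, so the spread includes true differences between times. The control's own spread is left out where the control was 1 pool.

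The 33 gene lists of pathways and cell types were written before the data were examined, as were the size rule and the rule for naming genes. Each list's median per time point is given with its percentile among 10000 random lists of the same size matched on mean intensity, as a description of these pools. For both limma fits the lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The naming rule took, per time point, the 6 highest and 6 lowest genes past the size rule that have a usable symbol, up to 10 each way from each limma fit, up to 4 members of each list described, and Pgr, Esr1, Ltf, Igf1, Vegfa, Cdkn1a, C3 and Muc1 at all times. Cdkn1a and C3 were not matched by symbol, and their values come from probes whose description in the files gives the product. Chosen after their values were seen were Klf10, Jun, Ccl4, Cxcl14, Clca1, Alpl, Padi1, Fkbp11 and Hoxd4, and the genes that changed side between times. Klk, Sprr2 and haemoglobin genes have near-identical relatives whose transcripts can bind the same probe, so their values are uncertain as to the member.

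The steps were tested on simulated data made with the real genes and spreads. The size rule recovered 66 of 66 genes changed 4-fold at each of the 5 time points and 0 of 67 changed 1.5-fold, with 0 false calls among 19880 genes. A change of exactly 2-fold was recovered for 0 of 67. The simulated error was equal and opposite on the 2 arrays, so these results of 0 were fixed in advance. They do not measure the false calls of the rule or its reach at 1.5-fold and 2-fold. For the mean of the 5 time points, limma recovered 47 of 67 genes changed 1.5-fold, 59 of 67 changed 2-fold and 63 of 66 changed 4-fold among 19880, with 10 false calls. For late against early it recovered 30 of 67, 48 of 67 and 59 of 66, with 9 false calls. The simulated changes were equal at all 5 times, or at both late times, and the noise was independent between genes. These shares therefore do not measure limma's reach for genes whose response varies over time, nor its false calls where genes vary together. Alternatives covered background correction, loess, the filter on dim probes, the size threshold, the software's ratios and p-values, the value table, each array and each time point. Slide serial numbers fall into 2 runs, with both 30 min arrays and replicate 1 of 12 h in the second, and each slide holds 1 array. No column of per-sample values was left out.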

Results

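The series follows RNA levels in the uterus of ovariectomized mice over 24 h after estradiol, with a vehicle-treated control on every array. It holds 5 time points with 2 dye-swapped arrays each. The arrays measured 20726 genes, and between 89.4% and 95.7% of spots were well above background in the E2 channel and between 93.6% and 96.7% in the control channel. Median spot signals were 154 to 271 in the E2 channel over backgrounds of 53 to 72. Across genes, the turned ratios of the 2 arrays correlated at 0.33 at 30 min, 0.86 at 2 h, 0.92 at 6 h, 0.94 at 12 h and 0.86 at 24 h. Genes are not independent replicates in these correlations. Each time point is 1 pool per treatment, so the values below have no biological replicate, and all ratios are log2 of E2 over control.

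The 30 min arrays address the first response to the hormone. Gadd45g, a growth-arrest and stress gene, was 15.5-fold higher in the E2 pool (log2 ratio 3.95 ± 0.17). Cebpb, a leucine zipper transcription factor, stood at 1.87 ± 0.10, Gadd45b at 1.56 ± 0.03, the Ras-related gene Rasd1 at 1.34 ± 0.01 and Errfi1, a feedback inhibitor of the EGF receptor, at 1.27 ± 0.07. Of 38 immediate early genes measured, 6 were higher and 0 lower, also including Klf10 (1.25 ± 0.01) and Jun (1.22 ± 0.04), and the list's median of 0.20 lay at percentile 100 of random lists. Jchain, an immunoglobulin component of plasma cells, was higher too at 1.53 ± 0.03. Pigt, of glycosylphosphatidylinositol anchor synthesis, was the single gene past the rule on the lower side (-1.30 ± 0.15). In all, 19 genes were higher and 1 lower, 8 and 1 of them with a usable symbol. Markers of macrophages and dendritic cells had a median of 0.17 and markers of mast cells 0.18, both at percentile 100, with 0 of 21 and 0 of 11 past the rule. Smooth muscle markers had a median of -0.09 (percentile 0.18) and stroma markers one of -0.06 (percentile 0.84), with 0 of 13 and 0 of 14 past it. The count was 31 higher with the scanner software's ratios, 30 higher on replicate 2 alone and 6 lower on replicate 1 alone.

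At 2 h the immediate early genes were the group furthest from the control. Of 38 measured, 19 were higher and 0 lower, with a median of 1.26 (percentile 100). Gadd45g stood at 4.40 ± 0.38, Cebpb at 3.72 ± 0.21, the orphan nuclear receptor Nr4a1 at 3.26 ± 0.02 and Ier2 at 3.22 ± 0.01. The tissue kallikreins Klk1 (4.02 ± 0.17, 16.2-fold) and Klk1b5 (3.20 ± 0.01) were as far from the control. Among 32 known oestrogen-response genes of the uterus, 10 were higher, among them Greb1 (2.97 ± 0.19), Ramp3 (2.79 ± 0.13), the water channel gene Aqp5 (2.34 ± 0.14) and the angiogenic factor Vegfa (1.57 ± 0.20). The probes described as inhibin beta-B, Cdkn1a and C3 had no symbol and are not counted in this list at any time. At 2 h the first and second passed the rule (4.62 and 2.29) and that of C3 did not (0.35). On the lower side were Rgs2, a regulator of G protein signalling (-3.75 ± 0.21, 13.5-fold), the potassium channel gene Kcnj8 (-2.75 ± 0.07), Gas1 (-1.92 ± 0.04), Nr2f2 (-1.72 ± 0.03), Hoxa10 (-1.70 ± 0.00) and the Wnt antagonist Apcdd1 (-1.70 ± 0.05). Among 20 steroid receptors and coregulators, Nrip1 (1.99 ± 0.05) was higher, and Nr2f2 and Nr2f1 (-1.04 ± 0.03) were lower. Stroma markers, which include Hoxa10 and Nr2f2, had a median of -0.36 (percentile 0) with 2 of 14 lower. Epithelium markers had a median of -0.15 (percentile 0.08) with 1 of 18 higher and 0 lower. Medians were 0.13 for adipocyte markers (percentile 99.65) and 0.09 for macrophage and dendritic cell markers (percentile 99.78), with none past the rule.

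The 2 h pool had 239 genes higher and 53 lower, and 81.8% of those past the rule were higher. With the software's ratios 134 were lower and the share higher was 71.8%, and with a normexp offset of 16, 80 were lower.

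**Figure D1:**
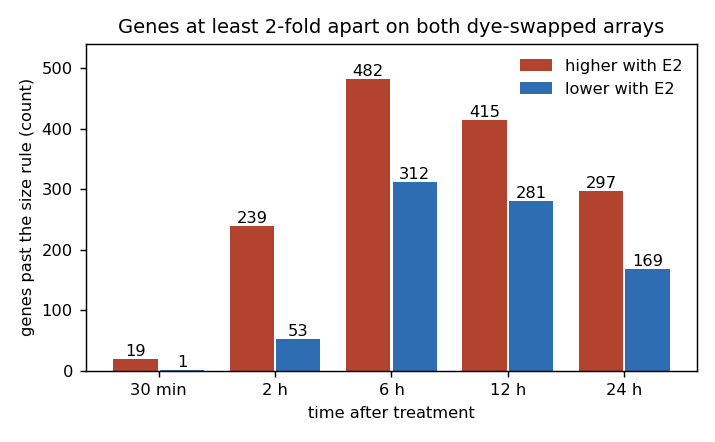
Bars give the number of genes past the size rule (vertical axis, count) at each time after treatment (horizontal axis), with genes higher in the E2 pool in red and lower in blue, from 1 pair of pools and 2 dye-swapped arrays per time. The higher genes number 19, 239, 482, 415 and 297 and the lower genes 1, 53, 312, 281 and 169.

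At 6 h, genes of protein folding, ribosome production and amino acid charging stood above the control together. Of 24 endoplasmic reticulum chaperones and related genes 12 were higher and 0 lower (median 1.10), led by Hspa5 at 2.41 ± 0.08, Dnajb11 at 2.13 ± 0.21 and Creld2 at 2.09 ± 0.04. Cytosolic and mitochondrial chaperones had 11 of 23 higher (median 1.13), with Hsph1 at 2.44 ± 0.05 and Hspa8 at 1.86 ± 0.05. Nucleolar and ribosome biogenesis genes had 7 of 24 higher (median 0.73), with Rrs1 at 2.22 ± 0.08 and Nip7 at 1.79 ± 0.14, and aminoacyl-tRNA synthetases had 3 of 8, Tars (2.30 ± 0.23), Yars (1.92 ± 0.05) and Lars (1.38 ± 0.04). These medians lay at percentile 99.99 for the synthetases and 100 for the others.

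The highest named genes at 6 h were Gadd45g (3.94 ± 0.10), Klk1 (3.55 ± 0.05), the arginine deiminase gene Padi2 (3.43 ± 0.01), Ramp3 (3.09 ± 0.25), Ccl2 (3.04 ± 0.25) and the spindle checkpoint gene Mad2l1 (2.83 ± 0.04). Among 38 chemokines and cytokines, 5 were higher, the monocyte chemoattractants Ccl2, Ccl12 (1.95 ± 0.02) and Ccl7 (1.17 ± 0.08) with Csf1 (1.22 ± 0.04) and Ccl4 (1.09 ± 0.02), and Cxcl14 was lower (-1.10 ± 0.05). Interferon-response genes had a median of -0.37 (percentile 0) with 3 of 24 lower, Iigp1 at -1.67 ± 0.33, Gbp3 at -1.54 ± 0.23 and Ifit3 at -1.37 ± 0.19. The lowest named genes were Fbxo32, a ubiquitin ligase subunit of muscle wasting (-3.68 ± 0.34, 12.8-fold), Dusp26 (-3.08 ± 0.35), the Wnt antagonist Sfrp2 (-2.62 ± 0.11), Mxra8 (-2.59 ± 0.27), Tgfbi (-2.46 ± 0.17) and Abtb1 (-2.45 ± 0.31). Igf1, a growth factor of uterine stroma, stood at 2.30 ± 0.31. Pgr, the progesterone receptor gene, was at 1.05 ± 0.10 and did not pass the rule.

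Beside these groups, stroma markers had a median of -0.65 (percentile 0) with 4 of 14 lower, among them Dcn (-2.20 ± 0.19) and Dpt (-1.93 ± 0.14). Adipocyte markers had 4 of 14 lower, with Fabp4 at -2.33 ± 0.09, Cfd at -2.32 ± 0.39, Adipoq at -2.07 ± 0.30 and Lpl at -1.07 ± 0.02. The haemoglobin genes Hba-a1 and Hbb-bt were higher at 1.24 ± 0.05 and 1.08 ± 0.07. Of 7 red cell markers 2 were higher, and the list median was 0.04 (percentile 78.5). The 6 h pool had 482 genes higher and 312 lower. The lower count was 631 with the software's ratios and 561 on replicate 1 alone.

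At 12 h, DNA replication genes joined the groups above the control. Of 32 measured, 6 were higher and 0 lower, with a median of 0.56 (percentile 100): Uhrf1 at 1.56 ± 0.04, Mcm2 at 1.49 ± 0.05, Pcna at 1.30 ± 0.19 and Gmnn, the licensing inhibitor, at 1.30 ± 0.01 were the highest. Mitotic genes had a median of 0.15 with 0 of 30 past the rule. Epithelium markers had a median of 0.29 (percentile 99.65) with 5 of 18 higher and 1 lower. Endoplasmic reticulum genes were higher for 16 of 24 (median 1.38), with Sdf2l1 at 2.93 ± 0.14, Dnajb11 at 2.45 ± 0.15 and the translocon subunit gene Sec61b at 2.27 ± 0.15. Oxidative phosphorylation genes had 5 of 28 higher (median 0.61), led by the cytochrome c gene Cycs at 2.58 ± 0.08. The highest named genes were Padi2 (3.88 ± 0.18), the cornified envelope gene Sprr2f (3.15 ± 0.16), Klk1 (3.14 ± 0.16), Igf1 (2.96 ± 0.11), Sdf2l1 and the nucleotide sugar transporter gene Slc35b1 (2.70 ± 0.22).

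The lowest named genes at 12 h were the matrix proteoglycan gene Dcn (-3.52 ± 0.17, 11.4-fold), Tgfbi (-3.41 ± 0.10), Inmt (-3.41 ± 0.02), Sparcl1 (-3.29 ± 0.04), Dusp26 (-3.24 ± 0.09) and the selenium carrier gene Selenop (-3.20 ± 0.09). Extracellular matrix genes went both ways, with 5 of 28 higher, such as Serpinh1 (1.76 ± 0.10) and Col5a1 (1.63 ± 0.01), and 4 lower. Stroma markers had a median of -0.39 with 3 of 14 lower, and adipocyte markers a median of -0.10 with 0 of 14, Adipoq, Fabp4 and Cfd lying at -0.30, -0.27 and -0.18. The 12 h pool had 415 genes higher (59.6% of those past the rule) and 281 lower. These counts were 706 and 560 with the software's ratios, the higher count was 641 on replicate 2 alone, and the share higher was 70.7% with median centring.

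At 24 h, mitotic genes stood well above the control. Of 30 measured, 16 were higher and 0 lower, with a median of 1.29 (percentile 100), led by Cdca3 (2.58 ± 0.13), Cks2 (2.35 ± 0.15), the cyclin gene Ccnb2 (2.11 ± 0.01) and H2ax (1.79 ± 0.21). DNA replication genes had 6 of 32 higher (median 0.50). Cholesterol synthesis genes had 9 of 16 higher (median 1.11, percentile 100), with Fdps at 3.04 ± 0.09, Sqle at 2.13 ± 0.12, Mvd at 2.13 ± 0.12 and Msmo1 at 2.09 ± 0.07. Their median had been 0.65 at 6 h and 0.36 at 12 h. Epithelium markers had a median of 0.68 (percentile 100) with 7 of 18 higher, such as Cldn7 (2.15 ± 0.09) and Krt7 (2.08 ± 0.08), and 1 lower, Cdh16 (-1.56 ± 0.18). Smooth muscle markers had a median of 0.32 (percentile 99.68) and macrophage and dendritic cell markers one of -0.14 (percentile 0.385), with 0 of 13 and 0 of 21 past the rule.

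The highest named genes at 24 h were Sprr2f (4.52 ± 0.03, 22.9-fold), Padi2 (3.76 ± 0.02), Fdps, the tetraspanin gene Tspan1 (2.84 ± 0.14), Sdf2l1 (2.80 ± 0.01) and the carbonic anhydrase gene Car2 (2.63 ± 0.30). The secretory genes Ltf (2.07 ± 0.00) and Clca1 (1.97 ± 0.15) were also higher, and Clca1 had been lower at 6 h (-1.68 ± 0.03) and 12 h (-1.95 ± 0.04). The lowest were Inmt (-4.18 ± 0.09, 18.1-fold), Tgfbi (-3.68 ± 0.08), the dendritic and B cell gene Cd83 (-2.81 ± 0.20), Sparcl1 (-2.75 ± 0.04), Dcn (-2.70 ± 0.15) and Dusp26 (-2.48 ± 0.20). Stroma markers had a median of -0.44 with 1 of 14 lower and 1 higher, the collagen gene Col1a2 (1.64 ± 0.04). Adipocyte markers were again lower for 3 of 14, Fabp4 (-2.04 ± 0.07), Cfd (-1.99 ± 0.29) and Adipoq (-1.61 ± 0.18). The 24 h pool had 297 genes higher (63.7%) and 169 lower. These counts were 512 and 346 with the software's ratios, the lower count was 278 on replicate 1 alone, and the share higher was 52.4% with median centring.

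**Figure D2:**
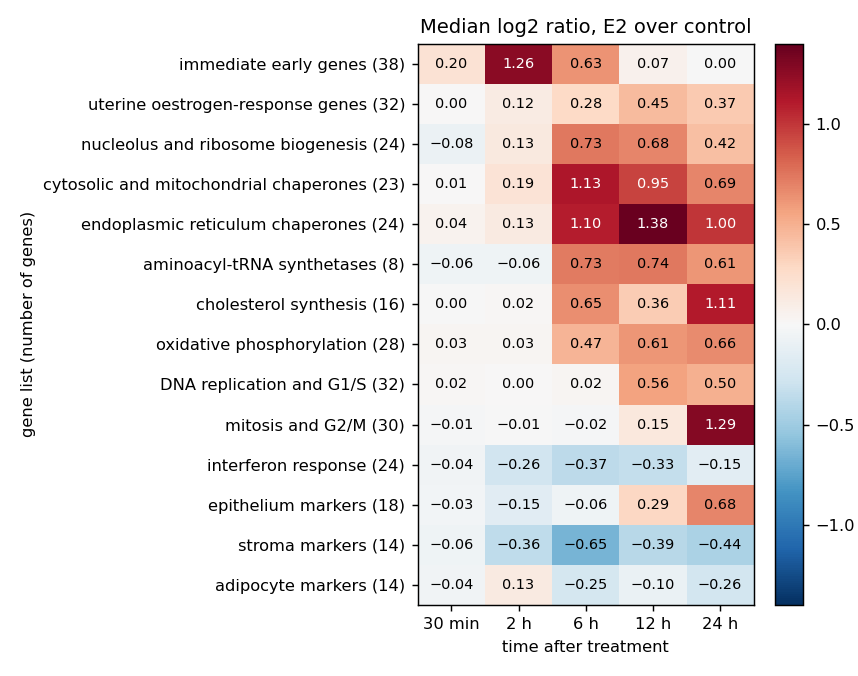
Each cell gives the median log2 ratio of E2 over control of 1 gene list (named at the left, with the number of genes) at 1 time after treatment (columns), from 1 pair of pools per time, with red above and blue below 0. Immediate early genes have their highest median at 2 h (1.26), endoplasmic reticulum chaperones at 12 h (1.38) and mitotic genes at 24 h (1.29).

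Of the genes fixed for report at all times, Igf1 passed the rule at 6, 12 and 24 h and Vegfa at 2, 6 and 12 h. Without background subtraction Vegfa no longer passed at 12 h (1.05). Ltf passed at 24 h alone. Esr1, the oestrogen receptor gene, stayed between -0.06 and 0.03 at the 5 times, and Muc1 between -0.06 and 0.06. Pgr stood at -0.08, 0.19, 1.05, 0.85 and 0.34 from 30 min to 24 h and passed at none. The probe described as the cell cycle inhibitor Cdkn1a (P21) stood at 0.89, 2.29, 1.85, 2.16 and 0.58 and passed at 2, 6 and 12 h, and that described as complement C3 stood at 0.75, 0.35, 0.04, 0.25 and 0.13 and passed at none.

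**Figure D3:**
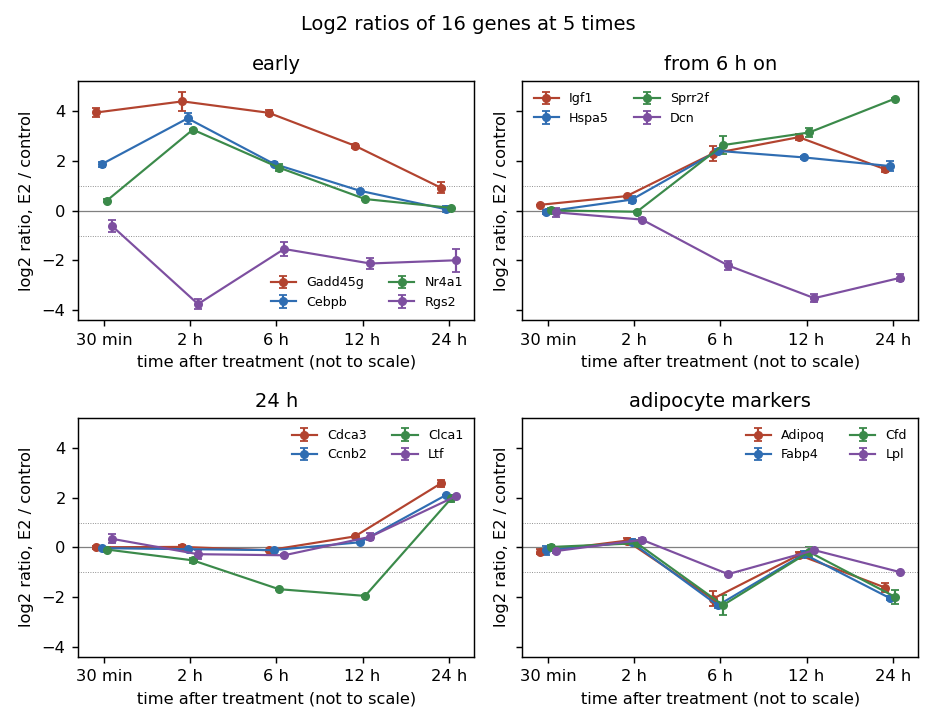
Log2 ratios of E2 over control (vertical axes) of 16 genes at 5 times after treatment (horizontal axes, not to scale), with 1 point per time for the mean of 2 dye-swapped arrays and bars for 0.5 of their difference. Dotted lines mark ratios of 1 and -1. Gadd45g was near 4 at 30 min already (3.95), whereas Ccnb2 was at 2.11 at 24 h, and Adipoq, Fabp4 and Cfd were low at 6 and 24 h but not at 12 h.

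Over all times, 1330 genes passed the rule at least once, 879 on the higher and 460 on the lower side, and 9 of these on both. Of the 870 genes higher only, 9 had their largest ratio at 30 min, 197 at 2 h, 284 at 6 h, 211 at 12 h and 169 at 24 h. Of the 451 lower only, 223 were lowest at 6 h and 123 at 12 h. With a 3-fold threshold more higher genes peaked at 2 h (94) than at 6 h (84), and with the software's ratios 351 and 280 higher genes peaked at 12 and 24 h and 451 lower genes were lowest at 6 h. At 2, 6, 12 and 24 h alike, 11 genes were higher, among them Klk1, Klk1b5, Padi1, Padi2, Alpl, Ramp3 and Fkbp11, and 11 lower, among them Rgs2, Kcnj8, Cd83, Apcdd1 and Hoxd4. A single probe, described as the inhibin beta-B subunit and chosen after its values were seen, passed at all 5 times at 1.33, 4.62, 4.12, 2.98 and 1.29.

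Of the 239 genes higher at 2 h, 16 were still higher at 24 h, where 3.57 would overlap between independent lists, and of the 53 lower genes 12, against 0.45. These overlaps were 32 and 37 genes with the software's ratios and 4 and 2 with a 3-fold threshold. Between 12 and 24 h, 179 higher and 131 lower genes were shared, against 6.20 and 2.39. Part of such an overlap can come from the control where the times shared it. A simulation of unchanged genes that takes all of the 30 min ratios as variation of a shared control gave 21.4 higher and 1.17 lower genes shared between 2 and 24 h and 21.7 and 1.25 between 12 and 24 h. It is no estimate of chance for these lists, since it gave 21.4 higher genes between 30 min and 24 h as well, where 1 was shared. The control channel differed between times by a median SD across genes of 0.19 (0.12 to 0.26 over the pairs of times), beside a dye-swap noise of 0.17 and 0.44 for the E2 channel.

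Taken over the 5 time points with limma, 18 genes were lower with E2 and 0 higher at an adjusted p under the threshold. The named ones were Wwtr1, a Hippo pathway coactivator, by a mean of -0.66 (SE 0.04, adjusted p = 0.048), Rgs1 by -0.64 (SE 0.04, adjusted p = 0.048), Cd209g by -0.45, the poly(A)-binding protein gene Pabpc1 by -0.42, Htatsf1 by -0.40 and Myom1 by -0.26. All 6 lay below 0 at 5 of 5 times, 30 min included, and their adjusted p was 0.048 or 0.049. At an unadjusted p under 0.05, limma had 2582 genes higher and 3098 lower, where 994 in all are due by chance. Ratios of the named genes were alike over the times, from -0.55 to -0.79 for Wwtr1 and from -0.23 to -0.30 for Myom1. A call needs a small spread over these same 5 values. The likeness and the common side therefore follow from the selection and are no further support. With 4 degrees of freedom the adjusted p of the named genes lay close to the threshold. If the times shared 1 control pool, a pool high for these genes would give such ratios too. The 5 values would then not be independent, and neither the p-values nor the 994 would hold. An effect of E2 and such a control cannot be told apart here. Without 30 min, 479 genes were higher and 1033 lower, and without 2 h, 6 h, 12 h or 24 h none passed, while the mean of Wwtr1 stayed between -0.63 and -0.69. None passed either with the software's ratios, median centring, no background subtraction, a normexp offset of 16, the stricter background filter or a robust spread model.

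At the level of lists, 13 of 33 were called over the 5 time points with the preset correlation. Endoplasmic reticulum chaperones (mean 0.75), cytosolic and mitochondrial chaperones (0.60), cholesterol synthesis (0.54), immediate early genes (0.53), uterine oestrogen-response genes (0.53), aminoacyl-tRNA synthetases (0.46), nucleolar genes (0.45), oxidative phosphorylation (0.42), mitosis (0.31) and DNA replication (0.26) rose. Stroma markers (-0.48), adipocyte markers (-0.28) and interferon-response genes (-0.24) fell. None of the 13 was called with an estimated correlation, where the smallest adjusted p = 0.69. A control pool shared by the times would bear on these list means as well. Adjusted over the list alone, 9 of 24 interferon-response genes fell, 5 of 38 immediate early genes rose and 3 fell, and 4 of 14 stroma markers fell. Of the adipocyte markers, whose median was -0.07 beside the mean of -0.28, 0 of 14 passed over the list alone, while 0 of 24 endoplasmic reticulum genes passed and 0 members of any of the 13 lists passed over all genes.

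Late against early times, limma called 0 genes in either direction (smallest adjusted p = 0.13), with 1232 higher and 959 lower at an unadjusted p under 0.05, where 994 are due by chance. With the preset correlation 11 of 33 lists were called. DNA replication genes had a mean of 0.65 late and 0.00 early, mitotic genes 0.67 and 0.06, oxidative phosphorylation 0.72 and 0.22, epithelium markers 0.50 and 0.03, and immediate early genes 0.07 late and 0.84 early. With an estimated correlation none was called, and DNA replication had the smallest adjusted p = 0.051. Adjusted over the list alone, 21 of 32 DNA replication genes rose and 0 of 30 mitotic genes passed. Counting 6 h as late called 250 genes higher and 193 lower, and treating all 10 arrays as samples, with the time point as a random block and a replicate block, called 482 and 229.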

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

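The lists and the late against early comparison were fixed before the data were examined, and the genes that changed side were picked out after their values were seen. Differences between late and early times were called by camera with the preset correlation for 11 lists, and with an estimated correlation for none of them (adjusted p from 0.051 to 0.71). As late minus early mean log2 ratio, 9 lists were higher late: endoplasmic reticulum chaperones by 0.67, DNA replication by 0.65, mitosis by 0.61, cholesterol synthesis by 0.56, oxidative phosphorylation by 0.51, epithelium markers by 0.46, cytosolic and mitochondrial chaperones by 0.42, glucose transport and glycolysis by 0.32 and nucleolar genes by 0.25. Immediate early genes were lower late (-0.77), as were macrophage and dendritic cell markers (-0.23), of which none passed the size rule at any time.

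For 7 named genes the E2 pools of different times lay on opposite sides of the control on both arrays, and these differences were not tested. The flow-responsive factor Klf2 stood at 1.86 at 2 h and -1.73 at 24 h, the clock gene Per2 at 1.31 and -1.11, and the serine protease gene Htra3 at 1.37 at 2 h, -1.99 at 12 h and -1.72 at 24 h. Pacsin3 stood at 1.74 at 2 h and -1.09 at 12 h. Others changed side upwards: Col1a2 from -1.28 at 6 h to 1.64 at 24 h, Clca1 from -1.68 at 6 h and -1.95 at 12 h to 1.97 at 24 h, and the deiodinase gene Dio2 from -1.27 at 2 h to 1.66, 1.48 and 1.81 at 6, 12 and 24 h.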

How the results depend on the processing

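The alternatives without the 6 and 24 h pools, on the first slide run alone and without genes that follow the adipocyte markers were chosen after seeing the data. Each time point rests on 1 pool per treatment, and probes near background have compressed ratios, which limits what the counts can show. Of 267 alternative values of counts, 179 stayed within 1.5 times and 88 moved further. Of 793 alternative values of named genes and lists, 682 kept their side of the threshold, 111 lost it and 0 reversed. Among the 682 are single-array values of genes past the size rule, which had to stay since the rule required both arrays. Under the size rule these values cover the highest, lowest and fixed genes with a usable symbol. The single loss among them was Vegfa at 12 h without background subtraction. Other list members named in the text were not put through these alternatives of the rule. Of 356 values of list members past the rule, 0 changed sign with the software's ratios, median centring, no background subtraction or an offset of 16. A lower threshold must raise counts and a higher one lower them, and the cause of the other moves was not tested.

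With a threshold of 1.5-fold, genes higher and lower numbered 50 and 13 at 30 min, 522 and 245 at 2 h, 1209 and 931 at 6 h, 1280 and 871 at 12 h and 903 and 611 at 24 h. With 3-fold they numbered 6 and 0, 100 and 13, 137 and 92, 97 and 77, and 83 and 34. Higher genes then peaked at the 5 times in 4, 94, 84, 52 and 59 cases and lower genes in 0, 8, 61, 47 and 10, and 4 higher and 2 lower genes passed at both 2 and 24 h. With the software's LogRatio, and likewise with the deposited value table, 31 genes were higher at 30 min, 134 lower at 2 h, 631 lower at 6 h, 706 higher and 560 lower at 12 h, and 512 higher and 346 lower at 24 h. With the LogRatio 351 higher genes peaked at 12 h and 280 at 24 h, lower genes peaked in 81, 451, 256 and 139 cases at 2, 6, 12 and 24 h, and 32 higher and 37 lower genes passed at both 2 and 24 h. The mean of the 2 arrays gave 2 lower genes at 30 min, and a normexp offset of 16 gave 80 lower at 2 h.

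On 1 array alone (without replicate 1 or without replicate 2), genes higher ranged from 23 to 30 at 30 min, 259 to 315 at 2 h, 547 to 678 at 6 h, 457 to 641 at 12 h and 393 to 438 at 24 h. Genes lower ranged from 1 to 6, 67 to 77, 348 to 561, 323 to 377 and 238 to 278. Over the 5 time points, the 18 lower limma genes became 0 with the LogRatio, the value table, median centring, no background subtraction, an offset of 16, the filter on both channels of all arrays, trend and robust moderation, replicate 2 arrays alone and without the 6 and 24 h pools. Scale normalization between arrays gave 15 higher and 135 lower, replicate 1 arrays alone 65 and 332, and the first slide run alone 355 and 807. With 1 time point left out, from 0 to 479 were higher and from 0 to 1033 lower, with the highest counts without 30 min and 0 without any other. Late against early, counting 6 h as late gave 250 higher and 193 lower. All 10 arrays with the time point as random block and a replicate block gave 482 and 229, but the replicate number is the dye orientation and these arrays are no separate samples. With an estimated correlation, 0 lists were called in either comparison.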

Other observations

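Several groups had members past the size rule on both sides. Among 28 redox and detoxification genes, Txnrd1 was higher at 6 h (1.44) and 12 h (1.27), and past the rule at 24 h as well, and Gpx2 at 24 h (1.75), while Gstm1 was lower at 6, 12 and 24 h (-1.74, -2.03 and -1.39). Of 13 retinoid genes, Aldh1a2, which makes retinoic acid, was higher at 6 h (2.57), 12 h (1.90) and 24 h (1.18), the binding protein gene Crabp1 was higher at 24 h (1.82), and Rdh5 was lower at 12 h (-1.11). Of 33 Wnt pathway genes, Wnt4 was higher at 2 h (2.22), and Sfrp2, Rspo1 (-1.70) and Fzd2 (-1.27) were lower at 6 h. Of 29 genes of angiogenesis and vascular permeability, Pgf (2.27) and Nos3 (1.70) were higher at 2 h, and Hpgd, which inactivates prostaglandins, was lower at 2, 6 and 12 h (-1.56, -1.57 and -1.58). A second Nos3 probe stood at 0.40 at 2 h. Among 18 aquaporin and ion channel genes, Aqp8 was higher at 6 h (2.04) and Aqp1 lower at 6, 12 and 24 h (-1.58, -1.57 and -1.79).

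In glucose metabolism, Hk2 (1.61) and Ldha (1.36) were higher and Ldhb lower (-1.66) at 6 h, among 20 genes. Of 13 common reference genes, Gapdh was higher at 6, 12 and 24 h (1.11, 1.14 and 1.14), as were Pgk1 at 12 and 24 h (1.32 and 1.15) and Hprt at 6 h (1.26). In the IGF pathway, Stc2 was higher (1.49) beside Igf1 at 24 h, and Igfbp6 (-1.50) and Ccn2 (-1.29) were lower. No marker of endothelium (16) or of eosinophils and neutrophils (17) passed at any time. Jchain was the single lymphocyte marker of 20 past the rule, at 30 min. Of smooth muscle markers 1 of 13 passed, Pcp4 at 6 h (-1.12), and of skeletal muscle markers 1 of 9, Tnni2 at 12 h (1.19) and 24 h (1.66).

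In the 3 patterns that follow, chosen after the result was seen were the test of the 30 min genes against 24 h, the wording of the adipocyte pattern without 12 h, the condition on the quartiles in the test of fat tissue, and the comparison of the 12 h test with 6 and 24 h. Adipoq, Fabp4 and Cfd were low at 6 and 24 h but not at 12 h, and of 97 genes lower at both 6 and 24 h these were the 3 with a 12 h ratio above -0.5, a limit set after their values were seen. With the software's ratios the median over these genes of the mean of 6 and 24 h minus 12 h was -1.99 (-1.92 with loess). That argues against the loess of the main values alone, but the software's ratios are LOWESS-normalized too. This difference therefore cannot decide on normalization of that kind. For less fat tissue in those E2 pools, the same difference over a second list of 13 fat-enriched genes had a median of -0.15. This met the limit set beforehand against this explanation (above -0.2) and missed the one set for it (-0.5 or below). Of the first list Lep, Lipe and Adrb3 did not follow (0.04, -0.09 and 0.04 at 6 h). Their mean log2 intensities of 8.88, 8.02 and 7.13 lay below the 11.4, 11.1 and 9.50 of Fabp4, Cfd and Adipoq. A loss may show less in dim probes, though Retn followed at 7.57. Dimness does not account for Pck1 and Scd1, which did not follow either (-0.19 and -0.08 at 6 h). Their intensities of 9.47 and 9.04 were close to those of Adipoq and Lpl (9.06). Pck1 and Scd1 are not among the fat-restricted markers, and neither are Fabp4 and Lpl, which followed. The quartiles of -0.44 and -0.05 over the second list reach past both sides of the limit of -0.2. That list's median lay at percentile 0.01 of random lists and Car3 followed (-1.24), as did Retn (-0.68, -0.18 and -0.67 at 6, 12 and 24 h) and Lpl (-1.07, -0.11 and -0.996). Fat carried along and an effect of E2 on fat genes therefore cannot be told apart with 1 pool per time, though all 14 markers were well above background in the control and no other list holds them. The wording set first included 12 h, where 0% of 7 fat-restricted markers lay at or below -1, but with 2 of 7 at 6 h and at 24 h that test decides nothing, and the list median at 12 h was -0.15 with the software's ratios and -0.10 with loess, which decides nothing either.

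Stroma markers lay below 0 for 11 of 14 at 12 h, or 78.6%, under the 80% set in advance as needed for a common shift. A lower share of stromal RNA in the E2 pool would lower them alike, but the SD between them was 0.94, with Dcn at -3.52 and Col1a2 at 0.25. That is over the 0.7 set in advance as the other limit for a common shift, so both were missed, and under the 1 set as the limit against it. A lower stromal share and regulation of single stromal genes by E2 therefore cannot be told apart.

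The 19 genes higher at 30 min had a median of 1.34. Their medians of 1.26 at 2 h, 0.46 at 6 h and 0.68 at 12 h go with a low control pool shared by all times, but that of -0.38 at 24 h, -0.28 of the 30 min value, argues against it as the sole source, with 18 of 19 genes under 0.25 of their 30 min value. The slide run shared by the 30 min arrays and replicate 1 of 12 h is argued against, unless a dye effect hid it. These genes differed between the 12 h arrays by -0.11, or -0.0858 of the 30 min median. The 2 arrays of 12 h also differ in dye orientation, which cannot be separated from the run with 1 pair. At 30 min, however, the dyes were exchanged within the run. An effect of the run on a dye would put the 2 turned ratios of a gene on opposite sides, which the size rule rejects. At 30 min 0 genes were 2-fold or more apart in that way. A separate control pool at 30 min that was low for these genes, a shared one beside an effect of E2 at 24 h, and differences between animals such as handling, stay open, as does a response to E2, which may be the source for the immediate early genes among them.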
